A study of Homo sapiens with 6 samples.

How the data were processed

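Expression was measured on Illumina Human-6 v2 bead arrays, which read 1 colour (Cy3), in 6 samples of total RNA from sorted HES2 cells: 3 that overexpressed a CD30 variant and 3 that overexpressed GFP. Per the labels' protocols, RNA was purified on columns, checked for quality and amplified before labelling. The groups and replicate numbers were taken from the sample titles, and each column of the tables was tied to a sample by its array position. All 6 arrays were on 1 chip, with the 2 groups in alternating positions, so chip and group were not confounded.

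The first deposited table holds, per the file headers, BeadStudio 2.3.41 output with no normalization and no error model. Its mean bead intensity is on a linear scale, and its detection column is a fraction from 0 to 1, given by the authors' software, that was turned into a detection p by subtracting it from 1. The number of beads and the bead standard deviation of each probe came from the same deposited table. The other 24 columns of per-sample values in it were not used. The second deposited table holds the authors' processed intensity values, on a linear scale, with the same rank order as the raw values on each array (Spearman 1.00 on every array) and medians of 12.53 on all arrays. Its distributions matched across arrays, as after quantile normalization; the step and background correction behind it are not given in the sources used here. The submitters' processing notes name BeadStudio and RMA, without roles.

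Probe intensities were background-corrected with the normexp model, using detection p in place of negative control probes, with an offset of 16, then quantile-normalized and put on a log2 scale (neqc approach, limma 3.58.1 in R 4.3.3, statmod 1.5.0). The deposited tables were used without control probes. Probes with a detection p under 0.05 on at least 3 of the 6 arrays were tested, 17218 in all. Populations were compared with limma's linear model and moderated test (lmFit and eBayes), two-sided, with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. Intensities near background compress fold changes. Where a probe was above background on no array of a group, the fold is given as a lower bound, the brighter group's mean against the dimmer group's mean of, per array, the higher of the probe's own value and the lowest value among detected probes. The arrays' number limits the precision.

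Of 48687 probes, 23675 had 1 gene symbol in the platform's annotation, 35 had several and 24977 had none; 23639 were updated through Entrez identifiers to the symbols of GRCh38.p14. Chromosomes come from that assembly, and no coordinates are given. No gene was named from a probe with several symbols, and 196 of the changed probes had no symbol. The transcripts XIST, TSIX, JPX and FTX and all Y-linked genes, 80 probes, were left out of every step. Genes were represented by their tested probe with the highest mean intensity, giving 11903 genes.

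The following choices were made before the data were examined: the test, the detection filter, 15 rows of alternatives, 29 gene lists and the rule for named genes. The rule names TNFRSF8, POU5F1, NANOG and SOX2; the 12 genes with the largest rise and the 12 with the largest fall among those with an adjusted p under 0.05 and no overlap between the groups' arrays; and up to 4 changed members of each list with the largest difference. Lists were tested with camera at a preset correlation of 0.01, with the correlation estimated, and with fry. No list passed camera with an estimated correlation. Fry, which asks whether a list's members move one way on balance and does not compare them with other genes, gave 7 lists past an adjusted p of 0.05, among them the epithelial and mesenchymal lists (both 0.0223) but not glycolysis and hypoxia (0.216). Counts by chromosome, over symbol families of at least 15 genes and without X-linked probes were added after the data had been seen.

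Replicate numbers are shared by both groups in the labels and follow the consecutive passages named in the series design. Deviations from the group means correlated at 0.12, 0.12 and 0.28 between arrays of the same number. Each was above 0.1 and the highest for its arrays across groups, so the numbers were taken to pair the samples. A fit with the replicate number as a block was run as an alternative. Arrays of the same number also held consecutive positions on the chip, so these correlations cannot tell a shared passage from position. No arrays held identical values; 74 to 117 of 48687 probes had equal raw intensities in any pair.

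The fit and the list test were tested on simulated data drawn from the means and residual spread of the 17218 tested probes in the comparison of CD30V with GFP. These were simulated as normalized log2 values without pairing, so background correction, normalization and the detection filter were not tested. Of 50 probes changed at each size, 30.0% were recovered at 1.5-fold, 58.0% at 2-fold, 96.0% at 4-fold and 98.0% at 8-fold, and 2.08% of the calls were false. A list of 18 genes, among 11903 genes, was shifted by 0.5 on the log2 scale. Camera recovered it with the preset correlation and with an estimated one (adjusted p = 0.0130), with no other list called under the preset one. The simulated genes were drawn independently of each other, so this could not test the preset correlation where members of a list move together. In the data the estimated correlation was 0.38 for the glycolysis and hypoxia list, 0.06 for the epithelial and 0.02 for the mesenchymal one. Permutation tests drew 100000 resamples and bootstrap intervals 10000. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.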

Results

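Gene expression was measured in HES2 cells, an established human embryonic stem cell line, that had been infected with a lentivirus carrying either a variant of CD30 (CD30V) or green fluorescent protein (GFP). CD30, encoded by TNFRSF8, is a receptor of the tumour necrosis factor receptor family. Cells of each population were collected by fluorescence-activated sorting at 3 consecutive passages, which gave 3 CD30V arrays and 3 GFP arrays, and total RNA was hybridised to a single-colour bead array that holds 6 arrays on 1 chip. The deposited table gave the mean bead intensity of 48687 probes per array, with a median of 39 beads behind each probe on every array. Between 17084 and 17911 probes per array had a detection p under 0.05. After normalization, arrays of the same population correlated at r = 0.989 to 0.992 (GFP) and 0.990 to 0.993 (CD30V) across the tested probes, and arrays of different populations at 0.975 to 0.980. The first principal component held 58.4% of the variance and placed the 3 CD30V arrays between 25.9 and 30.7 and the 3 GFP arrays between -30.4 and -23.6. The 3 passages of a population came from 1 infected culture or from several, which the labels do not state. The p-values of the probe tests below therefore measure the spread between these passages. Fisher's exact tests and permutation tests further below take genes as their units and do not measure that spread.

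The comparison of CD30V with GFP asked which transcripts differ between stem cells carrying the receptor variant and stem cells carrying the control protein. The single TNFRSF8 probe on the array was not above background on any of the 6 arrays, with a mean log2 intensity of 5.18 ± 0.24 (SD, n = 3) in CD30V cells and 5.11 ± 0.11 in GFP cells. Whether that probe lies within the transcript made from the construct is not given in the sources used here, so it does not check the labels. The core stem cell factor POU5F1 was measured at log2 15.22 ± 0.13 in CD30V cells and 15.18 ± 0.03 in GFP cells (adjusted p = 0.867), and its other 2 tested probes also did not pass. SOX2 was near background in both populations, with 5.79 ± 0.33 against 5.77 ± 0.11 (adjusted p = 0.968). The NANOG probe was not above background on any array. Each of these genes had a single probe, and whether it reports the transcript was not tested. The low values therefore do not show that SOX2 or NANOG was silent, or that either was unchanged.

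Of 17218 tested probes, 1189 (6.91%) differed between the populations at a Benjamini-Hochberg adjusted p under 0.05 in limma, 488 higher and 701 lower in CD30V cells. These probes stood for 384 genes that were higher and 519 that were lower among 11903 tested genes. Of the changed probes, 414 changed by at least 2-fold, 142 of them upward and 272 downward, and 40 by at least 8-fold, 16 upward and 24 downward. On 63 of the changed probes all 3 CD30V arrays and no GFP array were above background, and on 102 the reverse held. The 3 arrays of one population lay entirely above or below those of the other on 4793 probes (27.8%). Chance gives 10% if all 6 arrays are exchangeable, which the pairing by replicate number does not strictly allow. With 3 arrays per population the count depended on single arrays: it was 651 without CD30V replicate 1, 653 without GFP replicate 2, 703 without CD30V replicate 3 and 750 without CD30V replicate 2. A robust variance prior that follows intensity gave 1816.

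The genes with the largest rise were ZFP42, EDNRB, NMRAL1 and 9 genes of the zinc finger family. ZFP42 (also known as REX1, chromosome 4), a zinc finger protein widely used as a marker of undifferentiated stem cells, had a mean log2 intensity of 13.27 ± 0.20 (SD, n = 3) in CD30V cells and 7.05 ± 3.34 in GFP cells, a log2 difference of 6.21 ± 1.39 (SE, adjusted p = 0.0388). The GFP value was spread over the arrays, with 10.90 in GFP replicate 1 against 5.38 and 4.89 in GFP replicates 2 and 3, both of which were at background. EDNRB (chromosome 13), the endothelin receptor type B, was above background on all CD30V arrays and on no GFP array, and was at least 25.6-fold higher in CD30V cells (adjusted p = 1.68e-06). The zinc finger genes ZNF69, ZNF626 and ZNF585A were likewise above background on no GFP array and were at least 20.4-fold, 8.21-fold and 5.21-fold higher. ZNF569, above background on 2 GFP arrays, rose by 4.93 ± 0.15 (log2, SE) and ZNF93, above background on 1, by 4.39 ± 0.15. ZNF700, ZFP82, ZNF649 and ZNF273 rose by 2.68 to 3.26 on the log2 scale. Of these, ZNF700 was above background on 1 GFP array, ZFP82 and ZNF273 on 2 and ZNF649 on 3. All of these zinc finger genes lie on chromosome 19 in GRCh38.p14 except ZNF273, which lies on chromosome 7. NMRAL1 (chromosome 16) rose by 3.64 ± 0.80 (adjusted p = 0.0363), with 9.43 in GFP replicate 1 against 5.96 and 6.29 in GFP replicates 2 and 3. The calls of ZFP42 and NMRAL1 were lost without any one of the arrays other than GFP replicate 1, at adjusted p up to 0.118 and 0.101. With all 6 arrays they were also lost with the authors' processed values (0.105 and 0.0950) and with a robust variance prior that follows intensity (0.150 and 0.144). Without GFP replicate 1, ZFP42 was above background on no GFP array and was at least 217-fold higher, and NMRAL1 rose by 4.75 (log2).

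By log2 difference, the genes with the largest fall were led by COCH (chromosome 14), which encodes a secreted protein of the inner ear matrix. COCH was above background on all GFP arrays and on no CD30V array. It was at least 40.9-fold lower in CD30V cells, from a mean log2 intensity of 10.89 ± 0.18 (SD, n = 3) in GFP cells (adjusted p = 7.37e-07). For genes at background in CD30V cells only a bound is known, so the order among them is not settled. TMBIM4, PTGR1, CYB5R2, GPX7, SPIN3, PKIB and CT45A3 were also above background on no CD30V array. They were lower by at least 34.4-fold, 22.3-fold, 21.0-fold, 19.4-fold, 12.1-fold, 10.7-fold and 9.87-fold. FAM120B, above background on 1 CD30V array, fell by 5.35 ± 0.17 (log2, SE). PLIN2, which coats lipid droplets, fell by 3.72 ± 0.16 and was above background on 2 CD30V arrays. The metallothionein gene MT1G fell by 3.67 ± 0.65, and LRRN3 fell by 3.46 ± 0.18. Of these 12 genes, SPIN3 and CT45A3 lie on the X chromosome. Of the other 2 tested CT45A3 probes, 1 fell as well, and the other had a log2 difference of -0.65 (adjusted p = 0.273). With 1 array left out, the lower bound of CT45A3 ran from 6.90-fold without GFP replicate 3 to 18.7-fold without GFP replicate 1. The call of CT45A3 was lost without CD30V replicate 1, 2 or 3 or without GFP replicate 2, at adjusted p up to 0.0561, and that of MT1G without CD30V replicate 1 or 2, at up to 0.0555. With a robust variance prior that follows intensity the adjusted p was 0.0837 for CT45A3 and 0.0869 for MT1G, and with the authors' processed values it was 0.0521 for MT1G.

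**Figure D1:**
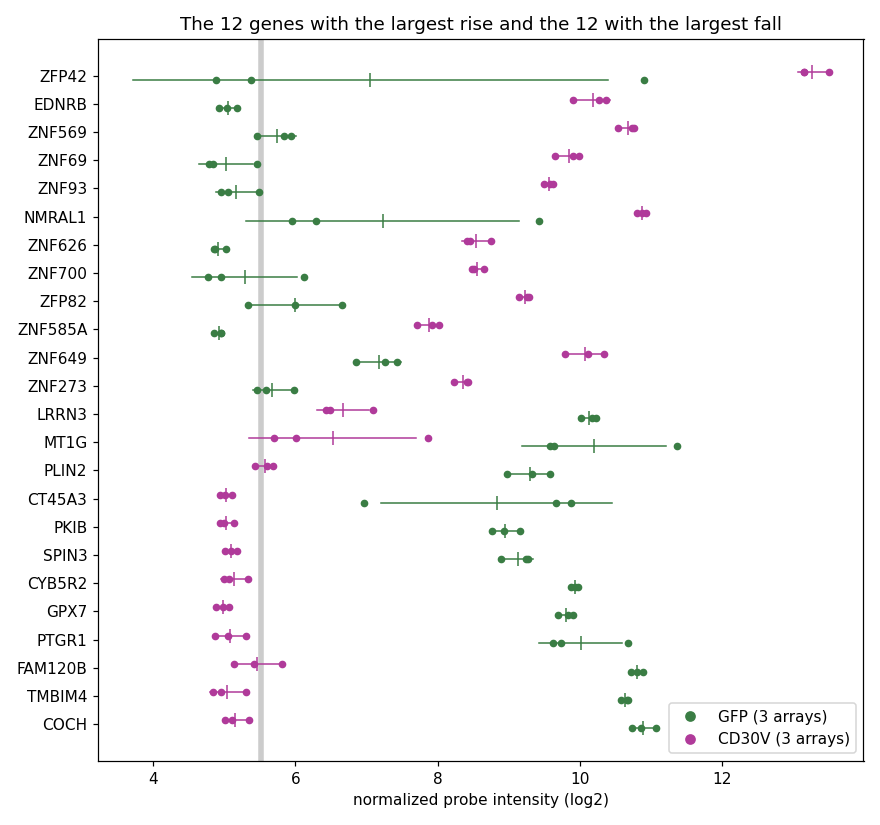
Normalized probe intensity (log2, horizontal axis) of the 12 genes with the largest rise (upper rows) and the 12 with the largest fall (lower rows) in CD30V cells; points are arrays, ticks and lines the mean ± SD of 3 arrays, and the grey band the lowest intensity above background over the 6 arrays. GFP replicate 1 lay at least 1 log2 unit from both other GFP arrays for ZFP42 (10.90), NMRAL1 (9.43), CT45A3 (6.96), MT1G (11.37) and ZNF700 (6.13), as CD30V replicate 3 did from the other CD30V arrays for MT1G (7.87).

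Among the pluripotency genes, 3 of 18 tested members rose and none fell. Besides ZFP42, NODAL, a signalling factor of the stem cell state, rose by 0.80 ± 0.11 (log2, SE, adjusted p = 0.00533), and the DNA methyltransferase DNMT3B by 0.57 ± 0.10 (adjusted p = 0.0157). The other tested DNMT3B probe gave 0.46 and did not pass (adjusted p = 0.201). Adjusted over the list alone, 3 members rose as well. As a group the list did not shift (median log2 difference 0.04, camera adjusted p = 0.236). Among nodal and TGF-beta targets, CER1 rose by 1.32 ± 0.18 together with NODAL, and the other 9 tested members did not pass; adjusted over the list alone, 3 rose and 2 fell (camera adjusted p = 0.435; fry 0.0223). The call of DNMT3B was lost without CD30V replicate 1, GFP replicate 2 or CD30V replicate 2, at adjusted p up to 0.0629, and the pluripotency list passed without GFP replicate 1 (0.0291).

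The list of epithelial genes shifted upward and that of mesenchymal genes downward in CD30V cells under the preset correlation. Of 18 tested genes of epithelial junctions and keratins, 2 rose and none fell, with GRHL2, a transcription factor of epithelia, up by 1.46 ± 0.23 (log2, SE) and the tight junction protein CLDN7 by 1.20 ± 0.11; adjusted over the list alone, 6 rose. The median difference of the list was 0.28 (camera adjusted p = 0.00436). With an estimated correlation camera gave p = 0.0523 before adjustment over the lists and 0.643 after it. Of 14 tested genes of mesenchymal transition, 3 fell and none rose. The intermediate filament VIM fell by 1.77 ± 0.15, the transcription factor ZEB2 by 1.57 ± 0.28 and the cadherin CDH2 by 1.02 ± 0.14; adjusted over the list alone, 7 fell. The median difference of that list was -0.34 (camera adjusted p = 0.00436). With an estimated correlation camera gave p = 0.0272 before adjustment over the lists and 0.643 after it. That correlation was 0.02, close to the preset 0.01, so members moving together do not alone account for the loss. Among 16 tested markers of fibroblast feeder cells, the proteoglycan LUM fell by 1.86 ± 0.29 and 15 did not pass; it was also the member that fell adjusted over the list alone. The feeder list had a median of -0.21 (camera adjusted p = 0.0883) and passed without CD30V replicate 2 or GFP replicate 3, at down to 0.0104; it also passed with array weights (0.0309) and with the mean of a gene's probes (0.0425). ZEB2 lost its call without GFP replicate 2 or CD30V replicate 2, at adjusted p up to 0.0574.

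Genes of glycolysis and the response to low oxygen had a median difference of -0.26 over 26 tested members (camera adjusted p = 0.00384; adjusted p = 0.730 with an estimated correlation). Of these, 2 fell and none rose, over all genes and adjusted over the list alone. NDRG1 fell by 1.68 ± 0.31 (log2, SE) and the peptide hormone ADM by 0.49 ± 0.11, both known to be induced by low oxygen rather than enzymes of glycolysis. Genes of oxidative phosphorylation had a median of 0.10 and no member of 24 passed, also adjusted over the list alone (camera adjusted p = 0.236; fry 0.0387). The call of NDRG1 was lost without CD30V replicate 1, 2 or 3, at up to 0.0662, and that of ADM without any one of 5 arrays, at up to 0.143; the exception was GFP replicate 3. ADM had an adjusted p of 0.0523 with the replicate number as a block, 0.0686 with the authors' processed values and 0.0678 without the detection filter.

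Of 14 tested interferon response genes, 3 rose and 5 fell, and adjusted over the list alone 3 rose and 8 fell. IFIT2, induced by interferon, was above background on no CD30V array and was at least 2.77-fold lower (adjusted p = 0.00226). IFITM2, a membrane protein that restricts virus entry, fell by 0.87 ± 0.12 (log2, SE). IRF7, a transcription factor of the interferon response, rose by 2.13 ± 0.45, and the antigen-presenting protein HLA-B by 0.86 ± 0.20. IRF7 was above background on 1 GFP array, GFP replicate 1 (6.87 against 5.09 and 5.05). Without that array IRF7 was at least 4.83-fold higher. IFIT1, IFITM1 and IFITM3, which fell, and PSMB8, which rose, were named after their values were seen. The list had a median of -0.45 (camera adjusted p = 0.0504) and passed without CD30V replicate 2 or GFP replicate 3, at down to 0.0384. It also passed by fry (0.0223) and under several other settings with all 6 arrays, from 0.00567 with the stricter detection filter to 0.0498 with an offset of 50. IRF7 was lost without any one of the arrays other than GFP replicate 1, at adjusted p up to 0.105, and with the authors' processed values (0.0959). HLA-B was lost without any one of the 6, at up to 0.133, and with all 6 under median scaling (0.0681), cyclic loess (0.0512), the authors' processed values (0.0895), no detection filter (0.0649) and without X-linked probes (0.0534), the last of which was added after the data were seen.

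The receptor family to which CD30 belongs signals through NF-kB. Of 17 tested NF-kB target genes, 2 fell and none rose: the chemokine CCL2 fell by 1.20 ± 0.15 (log2, SE) and the NF-kB inhibitor TNFAIP3 by 0.67 ± 0.11. Adjusted over the list alone 3 fell, and the list as a group did not pass (median -0.08, camera adjusted p = 0.435). None of 18 tested components of tumour necrosis factor receptor signalling passed (median 0.0025, camera adjusted p = 0.931), nor any of 12 anti-apoptotic genes (median -0.05, mean 0.01, camera adjusted p = 0.963) or 18 pro-apoptotic genes (median 0.15, camera adjusted p = 0.0857). The pro-apoptotic list passed by fry (0.0403), without the detection filter (0.0276) and with the mean of a gene's probes (0.0425). Adjusted over the signalling, anti-apoptotic and pro-apoptotic lists alone the counts were also 0. Of 17 tested p53 targets, PPM1D rose by 0.44 ± 0.10, and adjusted over the list alone 2 rose. The p53 list had a median of -0.03, a mean of 0.04 and a test direction upward (camera adjusted p = 0.933). PPM1D was lost without any one of the 6 arrays, at adjusted p up to 0.129, and had an adjusted p of 0.0523 with the replicate number as a block, 0.0936 under median scaling and 0.0580 without the detection filter.

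In the lists of markers of differentiated cells, few members passed over all genes. In the neural and ectoderm list, DCX, a microtubule protein of young neurons encoded on the X chromosome, fell by 0.60 ± 0.11 (log2, SE) among 11 tested members, and adjusted over the list alone 4 fell (median -0.39, camera adjusted p = 0.0504). Among 13 endoderm genes CER1 rose and APOA1 fell by 1.19 ± 0.27; adjusted over the list alone 1 rose and 2 fell (median -0.23, camera adjusted p = 0.236). IGFBP3 rose by 0.82 ± 0.15 among 11 trophoblast and amnion genes, where it was also the 1 that rose adjusted over the list alone (median 0.27, camera adjusted p = 0.326). No member passed among 12 genes of the primitive streak and mesoderm (median 0.24, camera adjusted p = 0.326) or 5 blood and lymphoid markers (median -0.05, mean 0.02, test direction upward, camera adjusted p = 0.971), also adjusted over each list alone. The neural list passed without GFP replicate 1, CD30V replicate 2 or CD30V replicate 3, at down to 0.00833, and under several settings with all 6 arrays, from 0.0225 with array weights to 0.0498 with an offset of 50. The trophoblast list passed without CD30V replicate 2 (0.0225), and its median ran from -0.0023 without CD30V replicate 3 to 0.57 without CD30V replicate 2, with 0.08 without GFP replicate 3 and 0.47 without GFP replicate 2. The endoderm median was -0.0028 without GFP replicate 2. DCX was lost without any one of 5 arrays, at up to 0.0880, the exception being GFP replicate 1, and APOA1 likewise, at up to 0.117, the exception being GFP replicate 3. IGFBP3 was lost without GFP replicate 1 or 2, at up to 0.0560. APOA1 had an adjusted p of 0.0877 with the replicate number as a block, 0.0854 with the authors' processed values and 0.0548 without the detection filter.

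Among targets of growth factor signalling, DUSP4 fell by 0.93 ± 0.14 (log2, SE) and PHLDA1 by 0.68 ± 0.11, while the cyclin CCND1 rose by 0.44 ± 0.10; these were the 3 of 16 tested FGF and ERK targets that passed, and adjusted over the list alone 1 rose and 4 fell (median -0.11, camera adjusted p = 0.251). DKK4, a secreted WNT antagonist, rose by 1.81 ± 0.40 among 16 WNT targets, of which 2 rose adjusted over the list alone (median 0.12, camera adjusted p = 0.555). No BMP target of 14 passed (median 0.10, camera adjusted p = 0.746), and no immediate early gene of 15 did (median -0.02, camera adjusted p = 0.604), also adjusted over each list alone. PHLDA1 was lost without CD30V replicate 1 (0.0570), DKK4 without CD30V replicate 1, 2 or 3 or GFP replicate 2, at up to 0.108, and with the authors' processed values (0.104), and CCND1 without any one of the 6 arrays, at up to 0.139. CCND1 had an adjusted p of 0.0550 with the replicate number as a block, 0.0680 under median scaling, 0.0592 with the authors' processed values and 0.0680 without the detection filter. The FGF and ERK list passed by fry (0.0223).

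Few members of the lists of growth and housekeeping genes passed the test. The replication helicase subunit MCM5 rose by 0.49 ± 0.11 (log2, SE) among 22 tested genes of S phase and DNA replication, and it was the 1 that rose adjusted over the list alone. That list had a median of 0.18 (camera adjusted p = 0.0726), and an adjusted p of 0.0462 with the replicate number as a block. It also passed without CD30V replicate 2 or GFP replicate 3, at down to 0.00628, and under 5 settings with all 6 arrays, from 0.0276 without the detection filter to 0.0461 without background correction. None of 22 mitosis genes passed (median 0.03, camera adjusted p = 0.931), nor any of 16 genes of cholesterol synthesis (median -0.13, camera adjusted p = 0.188), 21 of the unfolded protein and amino acid stress response (median 0.07, camera adjusted p = 0.262) or 24 cytosolic ribosomal protein genes (median -0.0023, camera adjusted p = 0.933). Adjusted over each of these lists alone, the counts were again 0. The chaperone HSPA1A fell by 1.00 ± 0.20 among 13 heat shock genes, and adjusted over the list alone 1 rose and 1 fell (median 0.07, camera adjusted p = 0.555). Of 15 histone and chromatin regulators, the DNA methyltransferase DNMT3A rose by 0.61 ± 0.12 with DNMT3B, and the same number rose adjusted over the list alone (median 0.01, camera adjusted p = 0.604). The other tested DNMT3A probe gave 0.21 and did not pass. The cholesterol list passed without GFP replicate 1 (0.0338) and with array weights (0.0396). MCM5 was lost without any one of 5 arrays, the exception being GFP replicate 3, at up to 0.121, and had an adjusted p of 0.0505 with the block, 0.0531 with the authors' processed values and 0.0512 without the detection filter. DNMT3A was lost without any CD30V replicate or GFP replicate 2, at up to 0.0742, and had 0.0671 without background correction, 0.0503 with a robust variance prior that follows intensity and 0.0661 with the mean of its probes. HSPA1A was lost without GFP replicate 1 or 2 or CD30V replicate 1 or 3, at up to 0.0925, and with the authors' processed values (0.0596).

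**Figure D2:**
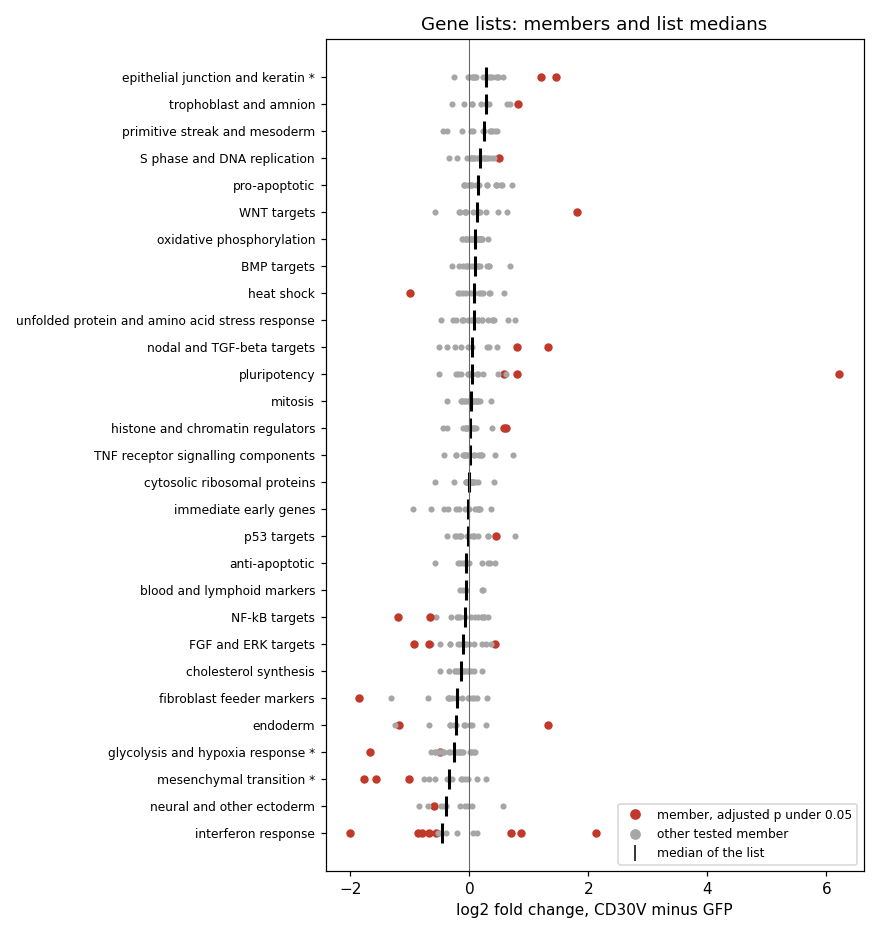
Log2 fold change (CD30V minus GFP, horizontal axis) of the tested members of 29 gene lists; points are genes, red where the adjusted p was under 0.05, black ticks are list medians, and an asterisk marks the 3 lists with a camera adjusted p under 0.05. The medians run from -0.45 (interferon response) to 0.28 (epithelial junction and keratin).

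Changed genes were also counted by chromosome and by symbol family, which was decided after the largest changes had been seen. Of 433 tested genes on the X chromosome, 116 (26.8%) fell and 11 rose, against 402 of 11464 autosomal genes (3.51%) that fell. The share of falling genes on the X chromosome was above that elsewhere (Fisher's exact test, two-sided, adjusted p = 1.48e-59 over 48 chromosome tests). Such tests by chromosome and family take genes as independent, so genes that moved together in 1 culture would make their p-values too small. The other chromosome past the threshold in these tests was chromosome 19. There 61 of 877 tested genes rose (adjusted p = 2.88e-07) and 20 fell, a lower share than elsewhere (adjusted p = 0.0164). Among genes without a ZNF or ZFP symbol, 26 of 712 on chromosome 19 rose (3.65%), a share that did not differ from elsewhere (Fisher's exact test, p = 0.205). Without X-linked probes the share that fell there was 2.28% against 3.34% elsewhere (Fisher's exact test, adjusted p = 0.499). The median log2 difference was -0.20 for X-linked and 0.02 for autosomal genes, and the X-linked genes that fell had a median of -0.93, with quartiles of -1.11 and -0.74, also with 5 of them at their lower bound. Of 362 tested genes with a ZNF or ZFP symbol, 50 (13.8%) rose and 11 fell, against 2.89% of other genes that rose. For the ZNF symbols alone, 47 of 347 rose (Fisher's exact test, two-sided, adjusted p = 4.98e-15 over 150 family tests). On chromosome 19, 35 of 165 tested zinc finger genes rose and 1 fell. With the stricter detection filter 25 of 261 zinc finger genes rose (Fisher's exact test, p = 1.42e-05), as did 25 of 253 with ZNF symbols (adjusted p = 0.000462). Without the detection filter the median was -0.07 for X-linked genes and 0.01 for autosomal genes. The autosomal median was also -0.02 under median scaling and 0.0045 with cyclic loess. The X-linked median lay below the autosomal one, and the zinc finger share that rose above that elsewhere, under every scaling and background alternative. Solute carrier genes were the other family past the threshold, with 18 of 224 that rose (adjusted p = 0.0259).

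The calls for X-linked genes that fell and for genes with ZNF symbols that rose passed in every alternative run that kept them. The call for risen genes of chromosome 19 was lost with the stricter detection filter (34 of 689, adjusted p = 0.589). The lower share of fallen genes there was lost without CD30V replicate 1 (0.123) or 2 (0.191) and with the replicate number as a block (0.349). It was also lost under 7 other alternatives, from 0.0850 without the detection filter to 0.712 with the stricter one. The solute carrier call was lost without CD30V replicate 1, 2 or 3 or GFP replicate 2 (1.00 each), with the block (0.168) and with the authors' processed values (1.00). It was also lost under 5 other alternatives, from 0.0761 without X-linked probes to 0.380 without the detection filter.

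Some of the counts by chromosome and family moved by over 1.5 times when CD30V replicate 1, GFP replicate 2, CD30V replicate 2 or CD30V replicate 3 was left out: in that order, 5, 5, 5 and 8 X-linked genes rose, 220, 216, 261 and 237 autosomal genes, 5, 5, 8 and 4 zinc finger genes and 11, 8, 15 and 10 genes of chromosome 19 fell, and 36, 41, 41 and 45 genes of chromosome 19 and 5, 7, 6 and 8 solute carrier genes rose. Without GFP replicate 1, 7 zinc finger genes and 10 genes of chromosome 19 fell, and without GFP replicate 3, 6 X-linked genes rose. Over the alternatives with all 6 arrays and X-linked probes, 5 to 17 X-linked genes rose, 7 with the replicate number as a block, and 294 to 656 autosomal genes, 7 to 17 zinc finger genes and 15 to 38 genes of chromosome 19 fell, while 25 to 63 zinc finger genes, 34 to 86 genes of chromosome 19 and 7 to 34 solute carrier genes rose.

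**Figure D3:**
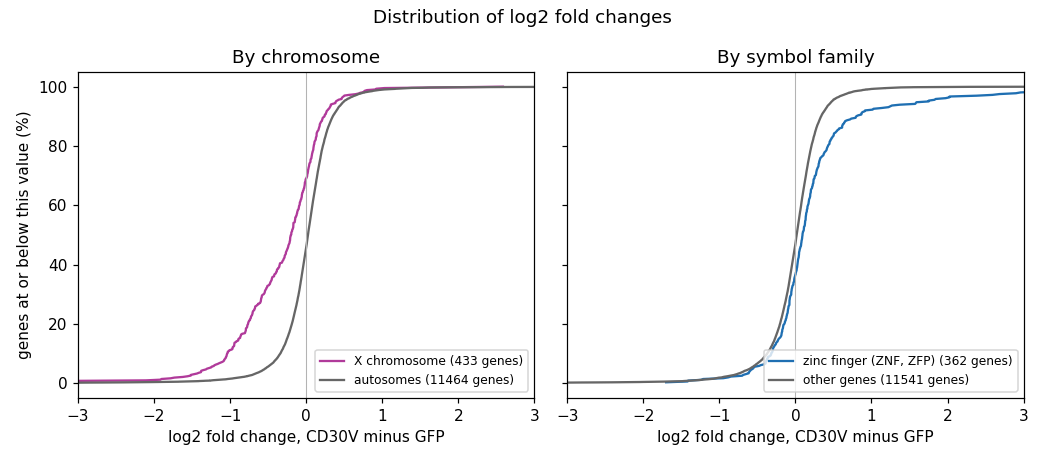
Cumulative share of tested genes (vertical axis, percent) at or below each log2 fold change, CD30V minus GFP (horizontal axis, shown from -3 to 3), for X-linked against autosomal genes (left) and for zinc finger against other genes (right). The X-linked curve lies to the left of the autosomal one (medians -0.20 and 0.02), and the zinc finger curve to the right at its upper end, where 50 of 362 genes rose.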

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

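The setting without X-linked probes was chosen after the data were seen. Of 52 named genes past the threshold, 32 kept their call in every alternative that tested them, and none reversed. The stricter detection filter tested 24 of the 54 named genes with a tested probe, so the others could not lose a call there. The counts of 1189 probes, 488 higher and 701 lower, moved by over 1.5 times, at least 1 of them, under 7 of 18 alternatives, 4 of which left out 1 array. A robust variance prior that follows intensity (trend and robust estimation changed together) gave 1816 probes, 786 of them higher. Array weights gave 764 higher, and no background correction 746. Leaving out 1 array gave 651 to 1045 probes, 233 to 406 higher and 403 to 639 lower. The cause was not tested, except that fewer samples were used where an array was left out. Of 29 lists, 3 passed with the preset correlation, 0 with an estimated one and 7 by fry. The number was 6 without background correction, without the detection filter and with that robust prior, 5 with an offset of 50 and with the stricter filter, 8 with array weights, 7 with the mean of a gene's probes and 3 to 8 with 1 array left out. Leaving out 1 array moved the median of 0 of these 3 lists by over 1.5 times, but of 21 of the other 26, and turned the sign of 11 of those. With the replicate number as a block, 1259 probes passed (506 higher, 753 lower), 1007 of them shared with the fit without it, so that 182 were lost and 252 gained; among the named genes and the lists it changed no call besides those of the 5 genes and the S phase list given above. Median scaling shared 1034 probes and 886 were shared with the fit to the authors' processed values. The TNFRSF8 probe was at background, and its difference of 0.06 lay between -0.07 and 0.17 throughout. Without X-linked probes 973 probes passed, 437 higher and 536 lower. Signal over background limits the dim probes: the 75th percentile of raw intensity was 1.66 to 1.75 times the background mean. The real split of the 6 arrays gave 1189 probes and the highest of the others 0; the split was 1 of 10, and 3 of the others also parted all 3 pairs, so the splits are too few for a share under 0.05.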

Other observations

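The tests of neighbouring genes, of zinc finger genes off chromosome 19, of evenness along the X chromosome and of GFP replicate 1 were chosen after the results were seen; the tests of escape genes, of X-linked bins and of scaling were written down after the pattern was noticed and before their own values were computed. Probes seen in 1 population only numbered 165, for 123 named genes. For 17 of these genes another probe was tested, 22 probes in all, of which 11 changed in the same direction, 11 did not pass and 0 changed the opposite way. Among X-linked genes with non-overlapping arrays, the next largest falls by log2 difference after SPIN3 and CT45A3 began with CDX4, a caudal-type homeobox gene, and PWWP3B. Both were above background on no CD30V array and were lower by at least 8.12-fold and 2.93-fold. XK (-1.90 on the log2 scale), the glypican GPC3 (-1.78), the tendon protein gene TNMD (-1.74) and PIN4 (-1.62) fell too; these 6 genes were named after their values were seen.

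The fall of X-linked genes was uneven along the chromosome. In 10 bins of 43 or 44 tested genes in chromosome order, the share that fell ran from 2.27% in the last bin to 62.8% in bin 7, a gap of 60.5 percentage points (permutation p = 1e-05, the smallest 100000 resamples can give), which argues against an equal change over the whole chromosome. Of 31 tested genes known to escape X inactivation 9 fell and 0 rose. Their median was -0.35 against -0.20 for the other X-linked genes, a difference of -0.16 (two-sided permutation p = 0.161). It also lay below autosomal genes (permutation p = 1e-05, again the smallest possible). The escape genes did not move together. ARSD (-1.41), GYG2 (-1.10) and TBL1X (-1.09) fell, while KDM6A (0.27), OFD1 (0.27) and DDX3X (0.19) lay above 0 and did not pass. By the rule written before the values were computed, the escape genes as a set went with a change in dosage of the whole chromosome. That rule used medians only and did not ask that each escape gene fall. With 9 of 31 past the threshold, it is weak evidence for such a change. The uneven bins, whose test was chosen after the results were seen, argue against a change of equal size. They cannot exclude a dosage change that lowered genes unequally. In 8 of the 10 bins more genes fell than among autosomes (one-sided Fisher p under the threshold), a count that leaves a change in one long stretch open. Bin 4 (9.30%, one-sided Fisher p = 0.0640) and bin 10 did not pass, so the bins that passed were not 1 unbroken run. The median log2 difference was -0.84 in bin 7 and -0.05 in bins 1, 3 and 5, with the other bins that passed between these values. Scaling acts on all genes of an array whatever their chromosome, so its test could hardly move the pattern and is weak evidence. The X-linked median minus the autosomal one was at most -0.16 under the scaling and background alternatives, against -0.22. It was -0.09 without the detection filter, which adds dim probes. A difference between the cultures in the activity or copy number of all or parts of the chromosome may be a candidate explanation. It could be unrelated to the construct or follow from it, and these data do not separate these possibilities.

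Zinc finger genes rose on and off chromosome 19. On other chromosomes 15 of 197 rose (7.61%) against 2.84% of other genes there (Fisher's exact test, p = 0.000682), which argues against a property of chromosome 19 alone. The nearest tested genes of other families on each side of the risen ones on chromosome 19 were also counted, skipping zinc finger genes between. Of these 15 genes 0 rose (0%), against 35 of 165 zinc finger genes there (Fisher's exact test, p = 0.0453). This is weak evidence, near the threshold, against a gain of a stretch that holds these neighbours. A gain confined to a cluster of zinc finger genes would leave them unchanged and stays open. Small rises can also be missed, as 30.0% of simulated 1.5-fold changes were recovered. The family was enriched under every scaling and background alternative (highest Fisher's exact p = 9.67e-15), and less strongly with the stricter detection filter (1.42e-05). A shared loss of silencing of this family in CD30V cells, or its gain in GFP cells, may be considered as a hypothesis, for which no test was run.

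In GFP replicate 1, ZFP42 stood at 18.9% and NMRAL1 at 34.4% of the way from the other GFP arrays to the CD30V level. Over 17 other probes not detected on GFP replicates 2 and 3 and at least 4-fold higher in CD30V, the median was 0.988% (bootstrap 95% interval 0.154 to 2.81), with 4 probes above 10%, which argues against CD30V cells in that sample as the cause. The gaps were at least 19.3 bead standard deviations on 32 or more beads, which argues against the noise of few beads. A subset of GFP cells at that passage that expressed these genes may be a candidate explanation; no biological explanation was tested. Probes on which 1 array lay apart from an agreeing pair of the same population numbered 29 for GFP replicate 1, against 10 to 24 for the other arrays. GFP replicate 1 also lay toward the CD30V level for RNLS (7.89 against 5.02 and 5.46) and IRF7 (6.87 against 5.09 and 5.05). The same held for ZNF502 (7.31 against 5.39 and 5.85) and for CT45A3, which was lower there (6.96 against 9.67 and 9.87). GFP replicate 1 lay away from the CD30V level for MT1G (11.37 against 9.64 and 9.58) and HSPA2 (7.84 against 6.17 and 6.23). Whether the GFP culture changed between passages was not tested.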
